A study of Homo sapiens with 26 samples.

How the data were processed

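Total RNA of a human clear cell renal carcinoma cell line, 786-O per the series text, was measured on 26 Affymetrix U133 Plus 2.0 arrays. RNA was extracted with an acid phenol reagent, treated with DNase and purified on columns, and biotin-labelled cRNA was hybridised, per the labels' protocols. The deposited values are signal intensities per probe set on a linear scale, and the submitters' processing notes name MAS5, the Affymetrix method that summarises the probes of a probe set within each array. Its version and scaling target are not given in the sources used here. The labels state a floor of 20, a ceiling of 16000 and a filter that discards probe sets with a maximum over minimum below 3 or a maximum minus minimum below 100. The deposited table holds values below 20 and all probe sets, so the floor and the filter are not applied in it. No value exceeded 16000, so it cannot be told whether the ceiling was applied.

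The titles give 8 groups of 3 arrays (Blk, DMSO, 40, 41, 76, 77, PRC3 and WT8) and 2 single arrays (pTR and pTV). The series text describes untreated cells, DMSO-treated cells and cells treated with 4 HIF-2a inhibitor compounds. Blk was therefore taken as untreated and 40, 41, 76 and 77 as the compounds, by elimination. Doses, treatment times and the meaning of PRC3, WT8, pTR and pTV are not given in the sources used here. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. No columns were identical, and the highest correlation between any 2 arrays was 0.978, between DMSO replicate 2 and Blk replicate 2.

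The deposited columns were not all made alike. In 24 columns at least 99.97% of the values were whole multiples of 1 step per column, with a tolerance of 0.05 of the step, as rounded signals times 1 factor would be. In replicates 2 and 3 of compound 40 the shares were 10.1% and 9.71%, all 54613 values were distinct, and the medians were 26.95 and 26.95. Before the data were examined, it was fixed that signals would be used as deposited if the 2% trimmed means of all 24 replicated arrays lay within 10% of their median, and quantile normalized otherwise. Replicate 3 of compound 40 lay 13.3% above that median, so the signals of the 26 arrays were quantile normalized without the 62 control probe sets. Values were then set to at least 20 and at most 16000 and log2 transformed. Probe sets at or above the array median on at least 3 of the 24 arrays were kept, which left 35013 of 54613. Median signals ran from 20.2 to 27.4 per array, close to the floor, and between 16.7% and 20.8% of the kept values of an array were at the floor. The number of arrays limits the precision. A fold against a group with every array at the floor is a lower bound and is written as at least that many fold.

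Gene names came from the platform annotation, updated through the Entrez identifier with the RefSeq table of GRCh38.p14. Of 41091 probe sets with 1 gene, 41037 were found there, and 0 symbols changed. Of the kept probe sets, 28327 had 1 gene, 1297 had several and 5389 were unnamed here. No gene was named from a probe set with several genes. A gene was represented by its single-gene probe set with the highest mean log2 signal over the 24 arrays, which gave 15124 genes. No coordinates are given, because the files name no genome build.

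Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend). All 24 arrays of the 8 groups shared 1 spread estimate per probe set, with 16 residual degrees of freedom, and the Benjamini-Hochberg adjusted p was called below 0.05 over the 35013 probe sets. Fold changes are differences of mean log2 signals, and SE is that of the log2 change. Signals are given as mean ± SD of 3 arrays. The 27 gene lists, 485 entries in all, were fixed before the data were examined, and a list needed 3 measured members. They were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A score of a list is the mean log2 signal of its members on an array, and the difference between 2 groups is given with a 95% interval from the 24-array model. The genes at least 2-fold lower or higher in WT8 than in PRC3 were tested in the same way in the comparisons of the compounds and of DMSO. pTR and pTV, with 1 array each, were compared without a test, and a list was placed by the percentile of its median among 10000 random lists of the same size matched on mean signal.

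The named genes follow a rule fixed before the data were examined. Always eligible were EPAS1, VHL, HIF1A, ARNT and the HIF-2a targets. For each comparison the rule took the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap (10% of genes do so by chance with 3 against 3 arrays) and whose brighter group was at or above the 70th percentile of mean signal. It also took up to 4 called members of each list with a called shift, and for pTR against pTV the 10 highest and 10 lowest ratios. Genes outside this rule are marked as chosen after their values were seen.

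Data were simulated for the comparison of compound 41 with DMSO, with 35013 probe sets and 50 changed at each size. There limma recovered 32% of changes of 1.5-fold, 74% of 2-fold, 100% of 3-fold and 100% of 4-fold. It called 7 of 34788 unchanged probe sets. Recovery was not split by signal, so the recovered shares do not give the power for weak probe sets near the floor. A list of 25 genes shifted by -0.6 was called, and 0 of 50 unshifted lists were. The simulated genes varied independently of each other, so this does not test list calls among correlated genes.

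The replicate numbers in the titles were checked by the correlation of the deviations of same-numbered arrays from their group means. Every such correlation was above 0.1 for DMSO with Blk (0.293, 0.207 and 0.146), compound 41 with DMSO (0.206, 0.187 and 0.172), compound 76 with DMSO (0.275, 0.184 and 0.184), WT8 with PRC3 (0.457, 0.107 and 0.346) and compound 41 with compound 76 (0.188, 0.145 and 0.105), so the numbers were taken to pair the arrays there. The pairing rests on this check and its cut of 0.1, and not on the labels. The correlations of the other comparisons were lower in part but also positive. They were 0.141, 0.0769 and 0.0964 for compound 40 with DMSO, and 0.165, 0.165 and 0.067 for compound 77 with DMSO. An effect of the number is therefore not excluded there. The fit reported has no block, and a fit with the number as a block was an alternative, whose list tests were also run with an estimated correlation, and its score intervals computed, after seeing the data.

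The other alternatives were the signals as deposited, scaling by the median, a floor of 9.53 (the mean 30th percentile), no filter on low signals, the filter stated in the labels (4991 probe sets), a fit on 2 groups only, no trend, each array left out in turn, Blk as control, an estimated correlation and the mean over all probe sets of a gene for the lists, and no fold minimum for the WT8 genes. Where leaving out arrays left a group with 1 array, that array was assumed to vary like the other groups. Chosen after seeing the data were a floor of 50, compound 40 without arrays 2 and 3, WT8 without replicate 3 (also among the planned fits with 1 array left out), the WT8 genes without the fixed lists, and the HIF-2a list on arrays numbered 1 or on arrays numbered 2 and 3.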

Results

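Gene expression was measured on 26 arrays of 786-O cells, a clear cell renal carcinoma line that lacks functional VHL, the protein that marks HIF-alpha subunits for degradation, and therefore accumulates the transcription factor HIF-2a. The design compared untreated cells (Blk), vehicle (DMSO) and 4 inhibitors of HIF-2a translation known only by the numbers 40, 41, 76 and 77, with 3 arrays each. PRC3 and WT8, with 3 arrays each, are names widely used for 786-O sublines carrying an empty vector and wild-type VHL, which the labels do not state. pTR and pTV had 1 array each. The 2% trimmed mean signals ran from 80.1 to 95.5 per array. WT8 replicate 3 had a 3 prime over 5 prime signal ratio of 2.37 for ACTB and 1.32 for GAPDH, against at most 1.39 and 1.06 on the other arrays. EPAS1, which encodes HIF-2a, reached deposited signals of up to 869. Of the probe sets with 1 gene, the only one for HIF1A did not exceed 32.0 on any array, and was not among those kept. Probe sets with several genes or without a name were not searched for HIF1A.

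The effect of the vehicle was read from DMSO against Blk. In the fit reported no named gene was called, and EPAS1 measured 464 ± 81.5 with DMSO and 494 ± 72.8 in Blk (SD, n = 3). The targets VEGFA, a growth factor of blood vessels, and CCND1, cyclin D1, differed by -0.076 and -0.11 on the log2 scale, with SE of 0.29 and 0.19. limma called 0 of 35013 probe sets, and 794 had an unadjusted p below 0.05, a smaller share than the 0.05 expected of unchanged probe sets. Without Blk replicate 3 it called 2, without DMSO replicate 3 it called 1. The 25 HIF-2a targets had a median log2 change of -0.085 with no member called, over all genes or adjusted over the list alone (list test adjusted p = 0.0396, and adjusted p = 0.895 with an estimated correlation). That call ended without Blk replicate 1 (median -0.061), DMSO replicate 2 (-0.070) or DMSO replicate 3 (-0.016), and held at -0.19 without DMSO replicate 1 and -0.21 without Blk replicate 3. With the replicate number as a block, IGFBP3 (-0.77, SE 0.21) and PLIN2 (-0.46, SE 0.12) were lower with DMSO adjusted over the list alone (adjusted p = 0.0153 for both), though not over all genes, and the list had an adjusted p of 0.00170, or 0.326 with an estimated correlation. Interferon response genes had a median of -0.33 (adjusted p = 2.92e-04, and 0.700 as the adjusted p with an estimated correlation), a call that ended without Blk replicate 2 (-0.22) or DMSO replicate 1 (-0.13), and held at -0.52 without Blk replicate 1. Adhesion and epithelial genes had a median of -0.14 (adjusted p = 0.0396, and 0.426 as the adjusted p with an estimated correlation), a call that ended without Blk replicate 1 (-0.063) or DMSO replicates 1, 2 or 3 (-0.22, -0.13 and -0.083).

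In the fit over all 8 groups WT8 had the most calls, but with the 2 groups alone it had 19, against 374 for compound 41 and 126 for compound 76. CCND1 measured 97.4 ± 5.26 in WT8 and 925 ± 40.6 in PRC3 (SD, n = 3), 9.50-fold lower (SE 0.19 on the log2 scale, adjusted p = 2.54e-10). EGLN3, a prolyl hydroxylase that acts on HIF-alpha, was 17.9-fold lower, with 2 of 3 WT8 arrays at the floor. VEGFA was 6.22-fold lower, ADM (adrenomedullin) 7.87-fold, EDN1 (endothelin) 6.56-fold and SLC2A1, the glucose transporter GLUT1, 3.71-fold. Of the 25 HIF-2a targets, 16 fell and 0 rose, or 18 and 1 adjusted over the list alone, with a median of -1.23 (adjusted p = 3.84e-20, and adjusted p = 0.0241 with an estimated correlation). Among the targets not called were CITED2, EGLN1 and VLDLR, at 0.0011, 0.067 and 0.24 on the log2 scale. EPAS1 differed by -0.38 (SE 0.24, adjusted p = 0.489, and 0.108 with the block) and VHL by 0.15 (SE 0.27, adjusted p = 0.886). Whether the VHL probe set reads an introduced VHL cDNA was not checked.

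Other genes moved as far. The largest rises in WT8 included the chemokine CXCL5 (21.1-fold, SE 0.33), ASS1 of arginine synthesis (16.6-fold, SE 0.29, with 2 of 3 PRC3 arrays at the floor) and MAL2 (10.7-fold, SE 0.18). CHRDL1, a BMP antagonist, and CMPK2 were at least 14.4-fold and at least 10.8-fold higher, with all 3 PRC3 arrays at the floor. ACKR3, a chemokine receptor, and DENND2A were at least 12.2-fold and at least 10.5-fold lower, with all 3 WT8 arrays at the floor. F3, which encodes tissue factor, was 12.5-fold lower and the lipid enzyme LPCAT1 7.19-fold lower. Of 17 interferon response genes, 9 rose and 0 fell, including IFI44L (6.09-fold) and OAS2 (4.32-fold), with a median of 1.24 (adjusted p = 1.13e-07, but adjusted p = 0.155 with an estimated correlation). Of 30 cell cycle genes, 9 fell, including MCM7 (2.05-fold) and BUB1B (1.70-fold), with a median of -0.44 (adjusted p = 3.15e-12, but adjusted p = 0.114 with an estimated correlation). Of 18 glycolysis genes 3 fell, among them ENO2 (7.44-fold) and PFKP (2.29-fold), with a median of -0.29 (adjusted p = 0.00107, but adjusted p = 0.114 with an estimated correlation). That median was -0.15 without PRC3 replicate 1 and -0.049 without WT8 replicate 3 (adjusted p = 0.0387). With the replicate number as a block, the adjusted p with an estimated correlation was 0.0440 for the interferon list and 0.0381 for glycolysis, but 0.126 for the cell cycle. The block called 12 interferon genes higher, 12 cell cycle genes lower, and 5 glycolysis genes lower and 1 higher.

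Smaller shifts in WT8 were called for 4 more lists, and each was lost with an estimated correlation in the fit without a block. NRF2 targets had a median of 0.33 with GCLM alone called (adjusted p = 0.00107, and adjusted p = 0.114 with an estimated correlation). NF-kB and cytokine genes had a median of -0.24 with ICAM1 alone called (adjusted p = 0.0317, and adjusted p = 0.510 with an estimated correlation). Translation genes had a median of -0.16 with EIF4EBP1 alone called (adjusted p = 0.00859, and adjusted p = 0.0669 with an estimated correlation), and were at -0.094 without PRC3 replicate 1. The 3 fibroblast markers had a median of 0.38 with LUM alone called (adjusted p = 0.0337, and adjusted p = 0.114 with an estimated correlation). With the block the estimated correlation gave an adjusted p of 0.0440 for the translation list, but 0.126 for NRF2 targets and 0.123 for the NF-kB list, and the fibroblast markers were not called. It called 6 NRF2 targets higher, and 4 NF-kB and 2 translation genes lower. The call of the NF-kB list ended without PRC3 replicate 3 (-0.056) or WT8 replicates 1 or 2 (-0.24 and -0.12), but its median was -0.41 and -0.40 without PRC3 replicates 1 and 2, and -0.60 without WT8 replicate 3 (adjusted p = 6.13e-05). The call of the fibroblast markers ended without PRC3 replicates 1 or 3 (0.25 and 0.41) or WT8 replicate 3 (0.21), and held at 0.65 without PRC3 replicate 2 and 0.72 without WT8 replicate 1. In all, 1597 of 35013 probe sets were called in WT8 against PRC3, 822 higher and 775 lower, or 494 and 410 genes. With median scaling the balance turned, to 590 higher and 762 lower. The count was 3151 with the replicate number as a block, 19 with the 2 groups fitted alone and 1006 without WT8 replicate 2. Without WT8 replicate 3, whose RNA ratios stood apart, the HIF-2a targets had a median of -1.13 with 15 lower, interferon genes 1.42 with 10 higher, cell cycle genes -0.42 with 6 lower, NRF2 targets 0.36 and translation genes -0.11, all called. Of 46 called genes named by the rule, 36 stayed called in every fit with 1 array left out.

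Compound 41 changed the most genes of the 4 compounds. HMOX1, heme oxygenase 1, rose 29.0-fold, from 90.7 ± 16.7 with DMSO to 2684 ± 839 (SD, n = 3; SE 0.27, adjusted p = 1.89e-10). AKR1B10 rose 23.5-fold, AKR1C3 19.5-fold, AKR1C2 12.2-fold and AKR1C1 9.91-fold. These are aldo-keto reductases, and the AKR1C genes are near-identical paralogs whose probe sets can read each other. SLC7A11, the cystine transporter subunit, rose 6.42-fold. Of 20 measured targets of NRF2, the transcription factor of the oxidative stress response, 16 rose and 0 fell, or 19 and 0 adjusted over the list alone, with a median of 1.48 (adjusted p = 2.96e-42, and adjusted p = 2.26e-06 with an estimated correlation).

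HIF-2a targets were lower with compound 41. VEGFA fell 4.17-fold, from 1167 ± 256 to 275 ± 15.6 (SD, n = 3; SE 0.29, adjusted p = 1.94e-04), and CCND1 fell 2.14-fold (SE 0.19, adjusted p = 0.00172). CA12, IGFBP3, ITPR1 and BHLHE40 were also lower. ANGPTL4 rose 7.51-fold (SE 0.61, adjusted p = 0.00817), with 2 of 3 DMSO arrays at the floor. Of 25 targets, 6 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a median of -0.67 (adjusted p = 1.77e-07, but adjusted p = 0.157 with an estimated correlation). With the replicate number as a block, 13 fell and the adjusted p with an estimated correlation was 0.0204. The calls of VEGFA and CCND1 held in every fit with 1 array left out. That of ITPR1 ended in all 6 (log2 change nearest to 0 -1.41), and that of BHLHE40 in all but the fit without DMSO replicate 2 (-0.76). The call of IGFBP3 ended without DMSO replicates 1 or 3 or compound 41 replicate 2 (-1.16), that of CA12 without DMSO replicate 2 (-0.76) and that of ANGPTL4 without DMSO replicates 1 or 3 (2.60). EPAS1 measured 369 ± 154 against 464 ± 81.5, -0.40 on the log2 scale (SE 0.24, adjusted p = 0.526, and 0.112 with the block). The largest falls were those of SEMA6A, a semaphorin (8.21-fold, SE 0.44), LINC02274 (7.40-fold) and NEFL (4.46-fold). The neuronal enolase ENO2 fell 3.01-fold.

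Lists of cell growth and stress also shifted with compound 41. Of 30 cell cycle genes, 13 fell, among them CCNA2 (1.89-fold) and MCM7 (2.03-fold), with a median of -0.57 (adjusted p = 8.31e-21, and 0.0189 as the adjusted p with an estimated correlation). Of 17 p53 targets 6 rose, among them CDKN1A, which encodes the cell cycle inhibitor p21 (3.91-fold), and GDF15 (4.22-fold), with a median of 0.72 (adjusted p = 5.45e-08, and 0.0234 as the adjusted p with an estimated correlation). The 16 ER chaperones had a median of -0.27 with HYOU1 alone called (adjusted p = 3.05e-04, and 0.0181 as the adjusted p with an estimated correlation). Heat shock genes had a median of 0.42, with DNAJB1, BAG3 and HSPA4 called (adjusted p = 6.46e-05, but adjusted p = 0.157 with an estimated correlation). Of 7 metallothionein and zinc genes 5 fell (adjusted p = 3.68e-05, but adjusted p = 0.183 with an estimated correlation). The 13 cholesterol synthesis genes had a median of -0.69 with INSIG1 alone called (adjusted p = 2.10e-07, but adjusted p = 0.219 with an estimated correlation). NF-kB and cytokine genes had a median of -0.42 with RELB and IL1B called (adjusted p = 2.59e-04, but adjusted p = 0.272 with an estimated correlation). The autophagy and lysosome list had CTSL and SQSTM1 higher (2.22-fold and 2.15-fold; adjusted p = 0.0331, but adjusted p = 0.323 with an estimated correlation). Glycolysis genes had a median of -0.11 (adjusted p = 0.0434, but adjusted p = 0.274 with an estimated correlation), and fatty acid and lipid storage genes one of -0.14 (adjusted p = 0.0295, but adjusted p = 0.219 with an estimated correlation). With the block, the adjusted p with an estimated correlation was 0.0390 for the cell cycle, p53 and cholesterol lists, 0.0465 for ER chaperones, 0.0241 for heat shock and 0.0187 for NF-kB. The block also called more members, with 21 cell cycle, 8 cholesterol, 6 NF-kB and 2 ER chaperone genes lower, 8 p53 targets higher, and 6 heat shock genes higher and 1 lower. With the block and an estimated correlation, the adjusted p was 0.0769 for metallothioneins, 0.244 for the lysosome list, 0.0794 for glycolysis and 0.0652 for lipid storage. At the preset correlation the block still called these lists (list test adjusted p of 1.42e-05, 0.0366, 0.034 and 0.0167). The glycolysis call ended without DMSO replicates 1 or 3 (-0.062 and -0.12) or compound 41 replicates 1 or 2 (-0.066 and -0.088) and held at -0.18 without compound 41 replicate 3, where the NF-kB median was -0.28. The lipid call ended without compound 41 replicate 1 (-0.12) and held at -0.22 without DMSO replicate 2, and the lysosome call ended without DMSO replicate 2 (0.20) or compound 41 replicate 3 (0.21). Of 46 called genes named by the rule, 22 stayed called in every fit with 1 array left out. limma called 889 probe sets, 411 higher and 478 lower, or 258 and 247 genes. It called 364 higher and 312 lower with median scaling, and 327 and 479 with the signals as deposited. With the block it called 2335, and with the 2 groups alone 374. It called 419 and 489 without compound 41 replicates 1 and 3, and 489, 509 and 554 without DMSO replicates 1, 2 and 3.

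Compound 76 raised several of the genes that rose most with compound 41. AKR1B10 rose 31.0-fold, HMOX1 28.5-fold, AKR1C2 26.1-fold, AKR1C1 23.4-fold, SLC7A11 6.17-fold and the prostaglandin reductase PTGR1 5.26-fold (SE 0.21, adjusted p = 1.14e-07). NRCAM, a neural adhesion molecule, was at least 10.3-fold higher, with all 3 DMSO arrays at the floor. Of 20 NRF2 targets 15 rose and 0 fell, or 20 adjusted over the list alone, with a median of 1.62 (adjusted p = 2.95e-59, and 2.07e-07 as the adjusted p with an estimated correlation). Of 25 HIF-2a targets, VEGFA (2.58-fold), IGFBP3 (4.09-fold), ITPR1 (3.23-fold) and SLC2A1 (1.80-fold) fell and ANGPTL4 rose 5.82-fold, or 10 and 1 adjusted over the list alone. The list median was -0.60 (adjusted p = 2.70e-07, but adjusted p = 0.147 with an estimated correlation). With the block 11 fell and the adjusted p with an estimated correlation was 0.0177. The VEGFA call ended without DMSO replicates 1 or 2 or compound 76 replicates 2 or 3 (log2 change nearest to 0 -1.16), those of IGFBP3 and ANGPTL4 without DMSO replicates 1 or 3 or compound 76 replicates 2 or 3 (-1.65 and 2.23). The ITPR1 call ended without any of these or DMSO replicate 2 (-1.52), and that of SLC2A1 without DMSO replicate 1 or compound 76 replicate 3 (-0.74). CCND1 differed by -0.72 (SE 0.19, adjusted p = 0.0620), and EPAS1 measured 320 ± 109, -0.57 on the log2 scale (SE 0.24, adjusted p = 0.348). With the block both were called lower, EPAS1 with an SE of 0.14 (adjusted p = 0.0236) and CCND1 with one of 0.18 (adjusted p = 0.0241). SEMA6A fell 7.51-fold, LINC02274 5.23-fold and ENO2 4.24-fold.

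The other list calls for compound 76 were lost with an estimated correlation in the fit without a block. Metallothionein and zinc genes had 5 of 7 lower (adjusted p = 1.95e-07, but adjusted p = 0.0858 with an estimated correlation). Cell cycle genes had a median of -0.30 with MCM7 alone called (adjusted p = 7.21e-12, but adjusted p = 0.0858 with an estimated correlation). ER chaperones had a median of -0.24 (adjusted p = 0.0166, but adjusted p = 0.0858 with an estimated correlation). TGF-beta targets had TGFB2 and PMEPA1 lower (adjusted p = 0.0105, but adjusted p = 0.0858 with an estimated correlation). Cholesterol synthesis had a median of -0.30 (adjusted p = 0.010, but adjusted p = 0.737 with an estimated correlation). NF-kB and cytokine genes had a median of -0.36 with IL1B alone called (adjusted p = 2.31e-04, but adjusted p = 0.353 with an estimated correlation). The autophagy and lysosome list had SQSTM1 and CTSL higher (adjusted p = 0.0488, but adjusted p = 0.536 with an estimated correlation). With the block, the adjusted p with an estimated correlation was 0.0248 for TGF-beta targets and 0.0177 for NF-kB, but 0.0517 for metallothioneins, 0.149 for the cell cycle, 0.181 for ER chaperones and 0.346 for cholesterol, and the lysosome list was not called at the preset correlation. The block called 6 cell cycle, 4 NF-kB, 3 TGF-beta, 2 ER chaperone and 2 cholesterol genes lower, and 1 TGF-beta target higher. The TGF-beta call ended without DMSO replicate 3 (-0.24), the cholesterol call without DMSO replicate 1 (-0.20) or compound 76 replicate 2 (-0.18), and the lysosome call without DMSO replicates 2 or 3 (0.15 and 0.24) or compound 76 replicates 1 or 3 (0.22 and 0.12). Calls that held had medians of 0.15 (lysosome) without DMSO replicate 1, -0.15 (ER chaperones) without DMSO replicate 2, and -0.083 (ER chaperones), -0.52 (cholesterol) and -0.21 (NF-kB) without compound 76 replicate 1. Of 34 called genes named by the rule, 17 stayed called in every fit with 1 array left out. limma called 474 probe sets, 262 higher and 212 lower, or 154 and 115 genes, 1396 with the block and 126 with the 2 groups alone. Without DMSO replicates 1, 2 or 3 it called 267, 277 or 267, and without compound 76 replicates 2 or 3 it called 273 or 226.

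Compound 40 raised the same kind of genes by less. AKR1B10 rose 14.8-fold, AKR1C3 9.54-fold, HMOX1 8.91-fold (SE 0.27, adjusted p = 1.52e-06), AKR1C1 5.39-fold and SLC7A11 2.75-fold. Of 20 NRF2 targets 14 rose and 0 fell, or 17 adjusted over the list alone, with a median of 0.79 (adjusted p = 1.32e-35, and 7.25e-06 as the adjusted p with an estimated correlation). Of 25 HIF-2a targets 2 fell, or 3 adjusted over the list alone, namely VEGFA (2.46-fold, SE 0.29, adjusted p = 0.0366) and CCND1 (1.96-fold, adjusted p = 0.0158) over all genes. The VEGFA call ended without any of the DMSO arrays or compound 40 replicates 2 or 3 (log2 change nearest to 0 -1.12), and the CCND1 call without DMSO replicate 2 or compound 40 replicates 2 or 3 (-0.80). The HIF-2a list median was -0.36 (adjusted p = 5.45e-05, but adjusted p = 0.353 with an estimated correlation). With the block, although the numbers were not taken to pair these arrays, 10 targets fell and the adjusted p with an estimated correlation was 0.0414. EPAS1 differed by -0.057 (SE 0.24). Among the largest falls were NMU, the peptide neuromedin U (2.54-fold), the nuclear lamin LMNB1 (2.32-fold), SERPINA1 (2.22-fold) and MT1H (2.30-fold). Replicates 2 and 3 of this group were deposited with values made differently from the others, and had 3 prime over 5 prime ratios for ACTB of 1.32 and 1.25, against 1.09 for replicate 1. Without them the NRF2 median was 0.82 (adjusted p = 1.07e-25), the HIF-2a median was -0.12 (adjusted p = 0.627) and 25 probe sets were called, with the lone array assumed to vary like the other groups. That fit sets an array numbered 1 against DMSO arrays of all numbers, and replicate 1 had the highest HIF-2a score in every group. The arrays numbered 1 alone differed by a HIF-2a median of -0.34, and those numbered 2 and 3 by -0.43.

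Of 7 metallothionein and zinc genes 3 fell with compound 40 (adjusted p = 3.99e-08, but adjusted p = 0.154 with an estimated correlation). Cell cycle genes had a median of -0.22 with MCM7 alone called (adjusted p = 3.73e-07, but adjusted p = 0.353 with an estimated correlation). Interferon response genes had a median of -0.52 with OAS3 alone called (adjusted p = 7.44e-06, but adjusted p = 0.353 with an estimated correlation). NF-kB and cytokine genes had a median of -0.42 with no member called (adjusted p = 0.00409, but adjusted p = 0.494 with an estimated correlation). In the iron handling list HMOX1 and ALAS1 of heme synthesis rose, while its median was 0.073 (adjusted p = 0.0428, but adjusted p = 0.218 with an estimated correlation). The iron handling call ended without DMSO replicate 3 (0.027) or compound 40 replicates 1 or 3 (0.010 and 0.092), and the NF-kB call without compound 40 replicate 3 (-0.30). Calls that held had medians of 0.027, 0.15 and 0.14 (iron handling) without DMSO replicates 1 or 2 or compound 40 replicate 2, -0.80 (interferon) without DMSO replicate 1, -0.27 (NF-kB) without DMSO replicate 2 and -0.34 (cell cycle) without compound 40 replicate 2. Without compound 40 arrays 2 and 3 the medians were -0.86 (metallothioneins), -0.41 (cell cycle), -0.60 (interferon), -0.36 (NF-kB) and 0.15 (iron handling). Those of cholesterol synthesis and of the lysosome list were 0.32 and 0.23. These medians rest on 1 array, numbered 1, set against DMSO arrays of all numbers. With the block, the adjusted p with an estimated correlation was 0.0414 for metallothioneins and 0.0274 for NF-kB, but 0.288 for the cell cycle, 0.0732 for interferon and 0.174 for iron handling. Of 25 called genes named by the rule, 9 stayed called in every fit with 1 array left out. limma called 240 probe sets, 119 higher and 121 lower, and 214 with the signals as deposited, 154 higher and 60 lower. It called 6 with the 2 groups alone, 149 without the filter on low signals, 159 with median scaling (87 higher and 72 lower), 98, 50 and 122 without DMSO replicates 1, 2 and 3, and 622, 70 and 139 without compound 40 replicates 1, 2 and 3.

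Compound 77 changed the fewest genes. NQO1, a quinone reductase, rose 2.25-fold, from 1804 ± 26.6 to 4106 ± 692 (SD, n = 3; SE 0.13, adjusted p = 8.19e-05), PTGR1 rose 2.84-fold and BLVRB, a biliverdin reductase, 3.12-fold. The histone gene H2BC12 rose 5.13-fold and SEMA6A fell 5.97-fold. NQO1 was the only called NRF2 target of 20, or 3 rose adjusted over the list alone, with a median of 0.19 (adjusted p = 0.00330, but adjusted p = 0.278 with an estimated correlation). VEGFA differed by -0.29 (SE 0.29, adjusted p = 0.907), CCND1 by 0.10 (SE 0.19, adjusted p = 0.970) and EPAS1 by -0.0018 (SE 0.24). In the fit reported no HIF-2a target was called, over all genes or adjusted over the list alone, and the list median was -0.29 (adjusted p = 0.00465, but adjusted p = 0.407 with an estimated correlation). Without DMSO replicate 1 that median was -0.13 (adjusted p = 0.124), and without compound 77 replicate 3 it was -0.16 (adjusted p = 0.0290). With the block, although the numbers were not taken to pair these arrays, NDRG1, IGFBP3, LOXL2 and EGLN3 were called lower and ANGPTL4 higher (adjusted p of 9.74e-04, 0.00183, 0.0331, 6.90e-04 and 0.0147). The list test with the block had an adjusted p of 1.73e-05, but one of 0.124 with an estimated correlation.

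The p53 targets had a median of 0.56 with compound 77 and no member called (adjusted p = 7.38e-07, but adjusted p = 0.129 with an estimated correlation). Cell cycle genes had a median of -0.18, cholesterol synthesis -0.47, metallothionein and zinc genes -0.32, glycolysis -0.14 and fatty acid and lipid storage -0.24, with no member called in the fit reported. With the block 3 p53 targets were called higher, and 2 glycolysis genes and 1 cholesterol gene lower. The adjusted p of these 5 lists were 1.69e-06, 5.46e-04, 0.00465, 0.00906 and 0.0158, and with an estimated correlation the adjusted p were 0.278, 0.407, 0.401, 0.278 and 0.278. In the aryl hydrocarbon receptor list NQO1 rose and UGT1A6 fell 3.17-fold (adjusted p = 0.0222, but adjusted p = 0.278 with an estimated correlation). With the block that list was not called (list test adjusted p = 0.0900). The calls of the NRF2, glycolysis and lipid lists ended without compound 77 replicate 2 (0.062, -0.081 and -0.22). That of the metallothionein list ended without DMSO replicate 2 (-0.28) or compound 77 replicate 1 (-0.24), and that of the aryl hydrocarbon receptor list without DMSO replicate 3 (0.18). Calls that held had medians of -0.28 and -0.21 (cholesterol) without DMSO replicate 1 and compound 77 replicate 2, 0.34 (p53) without compound 77 replicate 2, and -0.27 (cell cycle) without compound 77 replicate 1. They were -0.093 (glycolysis) and 0.13 (NRF2) without DMSO replicate 3, 0.33 (aryl hydrocarbon receptor) without DMSO replicate 2, and 0.12 (NRF2) and 0.27 (aryl hydrocarbon receptor) without compound 77 replicate 3. Of 15 called genes named by the rule, NQO1, PTGR1 and H2BC12 stayed called in every fit with 1 array left out. limma called 60 probe sets, 43 higher and 17 lower, 0 with the 2 groups alone, 34 without the filter on low signals and 36 without the trend. It called 25, 34 and 25 without DMSO replicates 1, 2 and 3, and 125, 15 and 22 without compound 77 replicates 1, 2 and 3.

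In the 6 comparisons of DMSO, the compounds and WT8 with their controls, 8 lists had no called shift in the fit reported, namely ribosome biogenesis, ATF4 and amino acid response, immediate early genes, extracellular matrix, oxidative phosphorylation, and endothelial, leukocyte and other epithelial markers. The smallest adjusted p among them was 0.0705. With 1 array left out some were called. The ATF4 list was lower with compound 41 without DMSO replicate 3 (-0.36), with 76 without compound 76 replicate 1 (-0.34), with 77 without DMSO replicate 3 (-0.13), and in WT8 without WT8 replicate 1 (-0.31) or PRC3 replicates 2 or 3 (-0.18 and -0.22). Ribosome biogenesis was higher with 77 without DMSO replicate 2 (0.30) or compound 77 replicate 1 (0.28), and other epithelial markers were higher in DMSO than in Blk without Blk replicate 3 (0.33). Without WT8 replicate 3, immediate early genes were lower in WT8 (-0.63, adjusted p = 0.00206) and oxidative phosphorylation genes higher (0.096, adjusted p = 0.0220). With the block, calls were added for the ATF4 list with compound 41 and WT8 (adjusted p of 0.0419 and 0.0374), extracellular matrix in DMSO against Blk (0.0350), and immediate early and ribosome biogenesis genes with 77 (0.00164 and 0.00332). Those block calls were lost with an estimated correlation, with adjusted p of 0.592, 0.523, 0.150, 0.124 and 0.127. Between compounds, immediate early genes were called lower with 40 than with 77 (-0.36, adjusted p = 0.0489, but 0.672 as the adjusted p with an estimated correlation).

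Some lists called in 1 comparison were called in another only with an array left out. Interferon response genes were lower with compound 76 without DMSO replicate 1 (-0.51), and with 77 without DMSO replicate 1 (-0.45) or compound 77 replicate 2 (-0.28). Heat shock genes were higher in WT8 without WT8 replicate 1 (0.24) or PRC3 replicates 2 or 3 (0.20 and 0.21), and in DMSO against Blk without Blk replicate 2 (0.11). Cholesterol synthesis genes were lower in WT8 without PRC3 replicate 3 (-0.49). The autophagy and lysosome list was higher in WT8 without WT8 replicate 3 (0.27) and with compound 40 without compound 40 replicate 2 (0.16). The block added calls of heat shock genes in WT8 (adjusted p = 0.0253) and in DMSO against Blk (adjusted p = 0.0411) and of NF-kB genes with 77 (adjusted p = 0.0407), each lost with an estimated correlation.

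**Figure D1:**
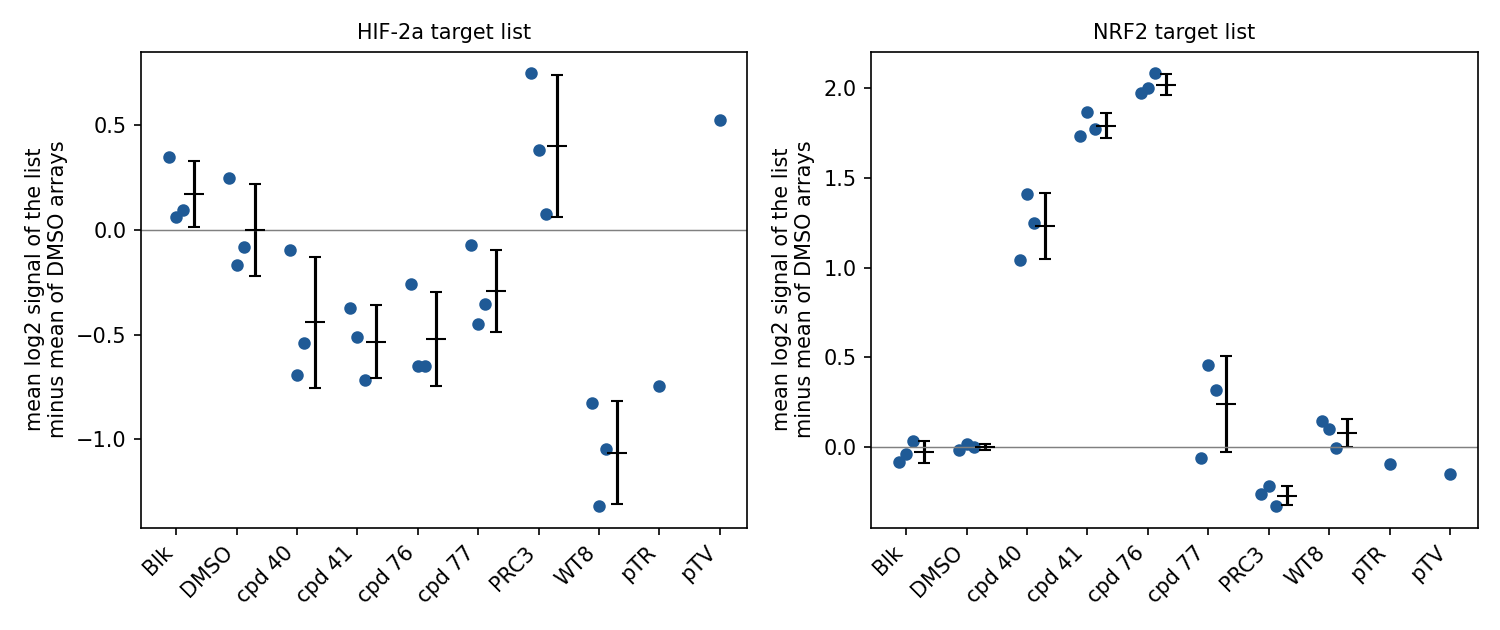
Mean log2 signal of the HIF-2a targets (left) and of the NRF2 targets (right) on each array, minus the mean of the DMSO arrays, by group. Points are arrays, and bars beside them are the mean and SD of 3 arrays. NRF2 scores run from 1.04 to 2.08 with compounds 40, 41 and 76, and from -0.058 to 0.46 with compound 77. In every group of 3 the highest HIF-2a score is that of replicate 1.

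The compounds were compared with each other directly, without knowledge of whether their doses matched. The NRF2 score with compound 76 exceeded that with compound 77 by 1.78 (95% interval 1.56 to 2.00), that with compound 41 exceeded it by 1.55 (1.33 to 1.77) and that with compound 40 by 0.99 (0.78 to 1.21). Compound 40 lay below compound 41 by -0.56 (-0.77 to -0.34) and below compound 76 by -0.78 (-1.002 to -0.57), and compound 41 below compound 76 by -0.23 (-0.45 to -0.011). The list tests of these differences held with an estimated correlation, with adjusted p of 1.70e-07, 1.28e-06, 9.08e-05, 0.0342 and 7.28e-04, except compound 41 against compound 76 (adjusted p = 0.202 with an estimated correlation). The mean NRF2 changes from DMSO were 1.79 with compound 41 and 2.02 with compound 76. Without AKR1C1, AKR1C2 and AKR1B10 they were 1.43 and 1.54, so much of the difference between these 2 compounds lay in those paralogs. In the model without a block, each 95% interval of a difference in HIF-2a score between 2 compounds included 0. The difference between compounds 41 and 76 was -0.014 (95% interval -0.43 to 0.40), between 40 and 41 it was 0.091 (-0.33 to 0.51), and between 41 and 77 it was -0.24 (-0.66 to 0.18). Intervals of that width do not show that the compounds act alike, and the spread behind them includes the effect of the array number. With the block the intervals were narrower, -0.22 to 0.19 between 41 and 76 and -0.11 to 0.30 between 40 and 41, and left out 0 between 41 and 77 (-0.45 to -0.037) and between 76 and 77 (-0.23, from -0.43 to -0.023), where the numbers were not taken to pair the arrays. The list test called HIF-2a targets lower with compound 41 than with 77 (median -0.22, adjusted p = 0.00118) and lower with compound 76 than with 77 (-0.11, adjusted p = 0.00610), with adjusted p of 0.520 and 0.517 with an estimated correlation. Those calls ended without compound 77 replicate 1 (-0.092 and -0.043), and the latter without compound 76 replicates 2 or 3 (-0.064 and -0.11), while it held at -0.26 without compound 76 replicate 1 and -0.28 without compound 77 replicate 2. Without compound 40 arrays 2 and 3, HIF-2a targets were called higher with compound 40 than with 41 (median 0.62, adjusted p = 3.30e-06) and with 76 (0.50, adjusted p = 1.74e-05), in a fit that sets an array numbered 1 against arrays of all numbers. That difference from compound 41 was also called without compound 40 replicate 2 (0.33), compound 40 replicate 3 (0.26) or compound 41 replicate 1 (0.25), and that from compound 76 without compound 40 replicate 2 (0.24) or compound 76 replicate 1 (0.24). HIF-2a targets were called lower with compound 40 than with 77 without compound 40 replicate 1 (-0.33). The p53 targets were higher with compound 41 than with 76 by a median of 0.67, and lower with 40 than with 41 by a median of -0.70, with adjusted p of 0.0156 and 0.0342 with an estimated correlation. TGF-beta targets were higher with compound 41 than with 76 (median 0.37), and ER chaperones lower with compound 41 than with 77 (median -0.21), with adjusted p of 0.0128 and 0.0304 with an estimated correlation. The latter was 0.109 with the block. With the block, compounds 41 and 76 differed in the p53 and TGF-beta lists with adjusted p of 0.0323 and 7.72e-04 with an estimated correlation, and also in the heat shock list (median 0.26, and 0.0249 as the adjusted p with an estimated correlation). The block list tests of 40 against 41 gave 0.034 (heat shock and TGF-beta) and 0.037 (p53, cholesterol and interferon) as adjusted p with an estimated correlation. That of NF-kB, lower with 40 than with 77 (median -0.50), gave 0.00185. The numbers were not taken to pair the arrays in these 2 comparisons.

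limma called 207 probe sets between compounds 40 and 41 (65 higher with 40), 44 between 40 and 76 (10 higher with 40), 154 between 40 and 77 (68 higher with 40), 39 between 41 and 76 (24 higher with 41), 158 between 41 and 77 (103 higher with 41) and 166 between 76 and 77 (117 higher with 76). With the replicate block, compounds 41 and 76 differed in 204. Many of these counts moved by over 1.5 times with 1 array left out. Between compounds 40 and 41 it was 529, 62 and 106 without compound 40 replicates 1, 2 and 3, and 60, 68 and 57 without compound 41 replicates 1, 2 and 3. Between 40 and 76 it was 241 and 24 without compound 40 replicates 1 and 2, and 23 and 11 without compound 76 replicates 2 and 3. Between 40 and 77 it was 459, 45 and 66 without compound 40 replicates 1, 2 and 3, and 42 and 33 without compound 77 replicates 2 and 3. Between 41 and 76 it was 18 without compound 41 replicate 1, and 24 without compound 76 replicates 1 or 3. Between 41 and 77 it was 93 and 85 without compound 41 replicates 1 and 3, and 103 and 97 without compound 77 replicates 1 and 3. Between 76 and 77 it was 105 and 76 without compound 76 replicates 2 and 3, and 102 and 96 without compound 77 replicates 2 and 3. With the signals as deposited, where the median of all probe sets was higher by 0.11 with compound 40 than with 41, the share higher with compound 40 moved from 31.4% to 61.8% against 41, from 22.7% to 51.1% against 76 and from 44.2% to 71.7% against 77. With median scaling, the share higher with compound 41 than with 77 moved from 65.2% to 75.4%, and the share higher with compound 40 than with 77 from 44.2% to 52.7%.

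Genes called with all 4 compounds were few, and could not exceed the 27 genes called with compound 77. The called genes were MGST1, NQO1, BLVRB, PTGR1 and FTH1P5, a ferritin heavy chain pseudogene whose probe set can read the parent gene, all higher, and PPP1R14C, lower. These 6 were named after their values were seen, where the rule for named genes does not hold them. PTGR1 rose between 2.38-fold and 5.43-fold and NQO1 between 2.25-fold and 3.20-fold. PPP1R14C fell between 2.56-fold and 3.40-fold, with an adjusted p of 0.0499 for compound 77. Simulations of 4 unchanged groups against the same DMSO arrays gave 0 such genes in each of 20 runs, and independent lists would give 1.59e-05 higher and 3.05e-06 lower. Unchanged groups have next to no calls to share, so the simulations could hardly end otherwise. The figures for independent lists leave out the shared DMSO arrays and spread estimates. Neither gives the overlap to expect of compounds that do have calls. With the replicate block 68 genes were called in all 4, and with Blk as control 21. Log2 changes of compounds 41 and 76 correlated across genes at 0.736, against 0.506 for unchanged groups that share DMSO, with a covariance of 0.108 against 0.0319 by simulation, and at 0.583 with 1 side set against Blk. Compounds 40 and 77 correlated least, at 0.450 against 0.505 by simulation, with a covariance of 0.0491 against 0.0319. Genes are not independent replicates, and the DMSO arrays were too few to split.

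The genes lower in WT8 were then read in the compound comparisons. Of 161 such genes, 36 fell and 2 rose with compound 41, 29 and 1 with compound 76, 9 and 0 with compound 40, and 1 and 1 with compound 77. Their median log2 changes were -0.52, -0.50, -0.33 and -0.27, and the adjusted p with an estimated correlation were 7.81e-04, 2.66e-04, 0.00527 and 0.0170. The 161 genes include HIF-2a targets such as CCND1 and EGLN3, so these results partly repeat those of the HIF-2a list. With DMSO against Blk the median was -0.091 with no member called (adjusted p = 4.31e-04, but adjusted p = 0.105 with an estimated correlation), and without DMSO replicate 2 it was -0.047. ENO2 and SEMA6A are among the genes that fell with compounds 41 and 76 and in WT8, where SEMA6A fell 4.95-fold. The 225 genes higher in WT8 had medians of 0.15 with compound 76 (adjusted p = 5.29e-04, but adjusted p = 0.0627 with an estimated correlation) and 0.14 with compound 41 (adjusted p = 0.0175, but adjusted p = 0.189 with an estimated correlation). The latter call ended without DMSO replicate 1 (0.083) or compound 41 replicate 3 (0.021), and for compound 76 the median was 0.089 without DMSO replicate 1. The medians were 0.069 with compound 77, -0.0016 with compound 40 (mean 0.040, on the higher side in the test) and -0.075 with DMSO against Blk (adjusted p = 0.00289, but adjusted p = 0.105 with an estimated correlation). With the block, which names 209 genes lower and 272 higher in WT8, the adjusted p with an estimated correlation was 0.0394 for the higher genes with compound 76, 0.160 for those with 41, and 0.00941 (lower) and 0.0175 (higher) for DMSO against Blk, at medians of -0.10 and -0.078. Of genes called in both comparisons, 105 of 124 went the same way with compound 41 and in WT8, and 79 of 88 with compound 76, where 30.2 and 16.1 shared calls were expected of independent lists. The comparisons share 1 spread estimate per probe set, which those expectations leave out, so the excess of shared calls does not by itself show a shared response.

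**Figure D2:**
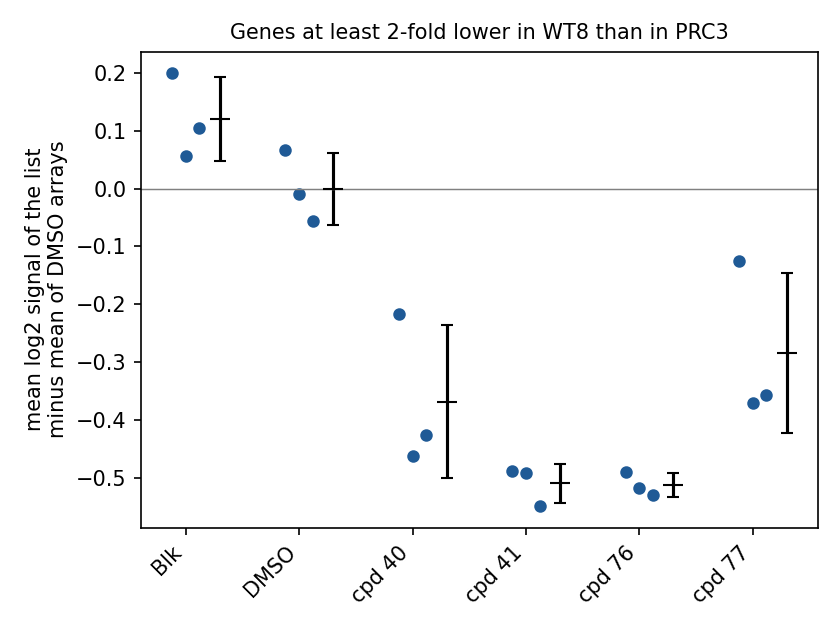
Mean log2 signal of the 161 genes at least 2-fold lower in WT8 than in PRC3, on each array of untreated, DMSO-treated and compound-treated cells, minus the mean of the DMSO arrays. Points are arrays, and bars beside them are the mean and SD of 3 arrays. The score lies below DMSO by -0.51 with compounds 41 and 76 (95% intervals -0.71 to -0.31 and -0.71 to -0.32).

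pTR and pTV were compared without a test, as each had 1 array and the labels do not explain the names. HIF-2a targets were lower in pTR, with a median log2 ratio of -1.06 over 25 genes, below all 10000 random lists. The random lists do not carry the correlation between the genes of a list. The percentile is therefore a rank, and does not tell how often 2 like arrays would differ as much. CCND1 was 7.60-fold lower, EGLN3 29.6-fold, CA12 11.5-fold and VEGFA 2.08-fold, while VLDLR was 2.25-fold higher. EPAS1 itself measured 344 in pTR and 789 in pTV, 2.29-fold lower. The highest ratios were those of COL6A3 (38.1-fold), CHRDL1 (34.5-fold) and NID2 (30.1-fold), and the lowest included BST2 (at least 33.1-fold) and TMEM47 (29.4-fold). The genes lower in WT8 had a median of -0.53 and those higher in WT8 a median of 0.30, at percentiles 0 and 100 of the random lists.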

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

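The tests of the NRF2 and HIF-2a patterns were chosen after the results were seen, and the counts over other splits of the arrays before.

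The rise of NRF2 targets with compounds 40, 41 and 76 was set against 2 technical explanations. Probe sets that read several AKR paralogs would leave little rise in the rest of the list, but without AKR1C1, AKR1C2 and AKR1B10 the smallest of the 3 medians was 0.77, with adjusted p of at most 1.61e-27. A fault of the DMSO arrays would leave no rise against untreated cells, but against Blk the smallest median was 0.95. An effect of the compounds may account for the pattern, as a hypothesis found in these data, and doses, times and cell damage stay open.

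The lower HIF-2a targets with compound 40 may come from replicates 2 and 3, whose deposited values were made differently. The score of replicate 1 was -0.094 relative to the DMSO mean, inside the range of the DMSO arrays (-0.17 to 0.25), and replicates 2 and 3 averaged -0.62, with an SD between replicates of 0.24. That goes with the explanation. The threshold of this test was changed once after its value had been seen, which left the outcome as it was. Against it, the arrays numbered 1 alone differed by a list median of -0.34, close to the -0.43 of arrays 2 and 3, and replicate 1 had the highest score in 8 of 8 groups, so an effect of the array number stays open. Replicates 2 and 3 also stood apart in the ACTB ratio of 3 prime over 5 prime signal, at 1.32 and 1.25 against 1.09 for replicate 1 and at most 1.10 for DMSO, though not in that of GAPDH (0.885 and 0.930, against 0.971 for replicate 1). They are the same arrays as those of the processing, so the test does not part it from RNA quality, and both stay open.

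The lower HIF-2a targets in WT8 were set against the RNA quality of WT8 replicate 3. Without that array the list median was -1.13, so it does not carry the difference. No other biological explanation was tested, and the labels do not say what WT8 is.

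For each replicated comparison the 6 arrays were split in all 10 ways into 3 and 3. With 10 splits no share below 0.05 can be reached. For WT8 against PRC3 the real split called 1597 probe sets and the highest other split 718, which put both arrays of 1 number on the same side, as did the split with 505. The numbers pair the arrays there, and the other 3 splits that part all pairs called at most 1, so these arrays have a structure by number besides the groups. Where the numbers pair the arrays of DMSO with Blk and of compounds 41 and 76 with DMSO and with each other, the other splits that part all pairs called at most 1 as well. For compounds 40, 41, 76 and 77 against DMSO the real splits called 240, 889, 474 and 60, and the highest others 2, 1, 1 and 0. For DMSO against Blk all 10 splits called at least as many as the real split, which called 0, and the highest other called 2. Between compounds the real splits called 207 (40 and 41), 44 (40 and 76), 154 (40 and 77), 39 (41 and 76), 158 (41 and 77) and 166 (76 and 77), and the highest others 3, 3, 2, 3, 1 and 1. In all comparisons but DMSO against Blk, 1 of 10 splits, the real one, reached the real count.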

How the results depend on the processing

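The floor of 50 and the omission of compound 40 arrays 2 and 3 were chosen after seeing the data. Signals lay close to the floor, with array medians of at most 27.4, which limits folds of weak genes. Below, counts are probe sets called, pairs of numbers name compounds, each single number stands for that compound against DMSO, and the cause was not tested except where fewer arrays, fewer or more probe sets, or a smaller spread enter by construction.

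With the replicate number as a block the counts were 1102 (40), 2335 (41), 1396 (76), 499 (77) and 3151 (WT8 against PRC3), 1154 (40 and 41), 348 (40 and 76), 911 (40 and 77), 204 (41 and 76), 651 (41 and 77), 490 (76 and 77), and 68 genes in all 4 compounds. All calls reported remained with the same direction, except 1 of 1597 in WT8. With the 2 groups alone they were 6, 374, 126 and 0 for 40, 41, 76 and 77, 19 for WT8, and 0, 0, 3, 0, 21 and 6 between compounds in the order above. Without the filter on low signals they were 3 (DMSO against Blk), 149 (40), 34 (77), 28 (40 and 76) and 64 (40 and 77). With the variation filter they were 849 (WT8), 137 (40 and 41), 97 (40 and 77) and 21 (41 and 76). With median scaling they were 159 (40) and 74 (40 and 77), with no trend 36 (77), 109 (40 and 41) and 75 (40 and 77), with a floor of 50 95 (40 and 77) and 73 (41 and 76). With Blk as control they were 106 (77) and 21 genes in all 4. Without compound 40 arrays 2 and 3 they were 25 (40), of which 17 were among the calls reported, 17 (40 and 41), 17 (40 and 76) and 14 (40 and 77).

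With 1 array left out the counts ran from 0 to 2 (DMSO against Blk), 50 to 622 (40), 419 to 685 (41), 226 to 381 (76), 15 to 125 (77), 1006 to 1869 (WT8), 57 to 529 (40 and 41), 11 to 241 (40 and 76), 33 to 459 (40 and 77), 18 to 32 (41 and 76), 85 to 134 (41 and 77) and 76 to 143 (76 and 77). The HIF-2a medians ran from -0.21 to -0.016 (DMSO against Blk) and -0.39 to -0.13 (77), those of the genes higher in WT8 from -0.12 to -0.035 (DMSO against Blk), 0.021 to 0.18 (41), 0.089 to 0.17 (76), 0.0043 to 0.080 (77) and -0.019 to 0.042 (40), and those of the genes lower in WT8 from -0.12 to -0.047 (DMSO against Blk).

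The HIF-2a call of DMSO against Blk ended at a median of -0.085 with the 2 groups alone, no filter, no trend or an estimated correlation, and at -0.15 with the variation filter. With an estimated correlation the HIF-2a calls of 40 (-0.36), 41 (-0.67), 76 (-0.60) and 77 (-0.29) ended, as did those of the genes higher in WT8 for 41 (0.14) and 76 (0.15) and, for DMSO against Blk, of the genes lower (-0.091) and higher (-0.075) in WT8. Without compound 40 arrays 2 and 3 the HIF-2a median of 40 was -0.12 and no longer called. With the 2 groups alone the genes lower and higher in WT8 were chosen anew, among the 19 probe sets called between WT8 and PRC3 in that fit. Medians of that setting therefore rest on far fewer genes than the 161 and 225 reported. For the genes higher in WT8, the call of 41 ended with the 2 groups alone (0.023), Blk as control (0.014), a floor of 50 (0.018) and median scaling (0.13), and that of 76 with the 2 groups alone (0.23) and Blk as control (0.077). They became called for 77 with the lower floor (0.080), the mean over probe sets (0.085), no filter (0.069) and no fold minimum (0.059), and for 40 with no fold minimum (0.027). With no fold minimum the DMSO against Blk calls of the genes lower (-0.023) and higher (-0.023) in WT8 ended. For DMSO against Blk the medians with the 2 groups alone were 0.0045 (lower in WT8) and 0.0052 (higher in WT8), of the other sign. They rest on the genes chosen anew, so they do not show that the 161 and 225 genes turned. The sign of the aryl hydrocarbon receptor list with 77 turned without the filter, to -0.0039.

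The following shares leave out the HIF-2a list in the comparisons with controls and the genes lower or higher in WT8, which are treated above. Of the remaining 54 list medians, 53 kept their side of the threshold with the deposited signals, 50 with the block and 15 with an estimated correlation. Direction was checked only for values called in the fit reported, and a value called in neither fit counts as kept. The 304 values of named genes include many not called in the fit reported. The called ones number 25 (40), 46 (41), 34 (76), 15 (77) and 46 (WT8 against PRC3). Of the 304, 275 kept their side with the block, where 29 more became called. Without the trend 270 did so and 34 calls were lost, and with the 2 groups alone 180 did so and 124 calls were lost. With 1 array left out, 278 of 324 list medians and 1530 of 1824 gene values kept their side, and 40 and 293 calls were lost.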

Other observations

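In pTR against pTV, several lists besides the HIF-2a targets stood at the edges of the random lists. All 13 cholesterol synthesis genes were lower in pTR, with a median of -0.63 (percentile 0.02). NF-kB and cytokine genes were lower in 14 of 16 (median -0.76, percentile 0), interferon response genes in 13 of 17 (median -0.60, percentile 0.01), p53 targets in 11 of 17 (median -0.49, percentile 0.01) and cell cycle genes in 26 of 30 (median -0.35, percentile 0.08). BST2 and TRIM22, both induced by interferon, were among the 10 lowest ratios. Oxidative phosphorylation genes were higher in 18 of 21 (median 0.24, percentile 98.5), ATF4 targets in 19 of 25 (median 0.31, percentile 98.9), metallothionein and zinc genes in 6 of 7 (median 0.41, percentile 98.9), immediate early genes in 11 of 14 (median 0.46, percentile 98.7) and adhesion and epithelial genes in 12 of 17 (median 0.34, percentile 97.7). These values describe 2 arrays and have no replicate check, and the random lists do not carry the correlation between the genes of a list.

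CHRDL1 and ASS1 were among the 10 largest rises both in WT8 against PRC3 and in pTR against pTV, and EGLN3 and F3 among the 10 largest falls of both. The overlap was noticed after the values were seen and was not tested.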
